A study of Enchytraeus albidus with 30 samples.

How the data were processed

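Whole adult worms of Enchytraeus albidus were kept for 4 days in spiked or clean soil, with 10 worms with a well developed clitellum and 25 g of soil per vessel, at 20 °C and 16 h light to 8 h dark. Per the labels, RNA was taken with Trizol, treated with DNase, and 0.5 µg was labelled with Cy3 as cRNA for Agilent 1-colour arrays. The 30 arrays are biological replicates in 9 groups, with 3 for each of 8 exposures (Cu, Ni, Cd and Zn, each at the EC50 and the EC90 for reproduction) and 6 controls. Each array holds 15744 spots, of which 536 are control spots and 15208 read the 1035 worm probes, with 14 or 15 spots per probe.

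Per the file headers, the deposited scanner output was made with Agilent Feature Extraction 10.5.1.1 on 16 arrays and 10.7.3.1 on 14, while the submitters' notes name 10.5.1.1 for all. Its processed, median, background and background-subtracted signals are deposited as intensity, on a linear scale. Its marks for spots well above background, for saturated spots and for uneven spots are deposited as 0 or 1, a unit of the kind other than intensity. The value table of the series matrix is given by the authors on the log2 scale. Its values ranked spots exactly as the background-subtracted signal did (rank correlation 1), filled 13384 to 15435 spots per array and had a median of 9.84 on every array.

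The log2 of the processed signal was averaged over the spots of each probe, and each array's 75th percentile over probe means was subtracted. A probe counted as above background on an array where over 50% of its spots were marked so. Probes above background on every array of at least 1 group were tested, which kept 892 and left out 143. Each probe was fitted with 9 group means on all 30 arrays (21 residual degrees of freedom) in limma 3.58.1 under R 4.3.3, with moderated t tests and Benjamini-Hochberg adjustment within each comparison. A probe was called at an adjusted p under 0.05, and adjusted p is limma's unless another test is named. The 19 comparisons were the 8 exposures against the controls, the EC90 against the EC50 of each of 4 metals, the metals pairwise over both concentrations, and Cu and Ni together against Cd and Zn together. Whether the step from EC50 to EC90 differed between metals was tested as an interaction, which was added after the comparisons had been fixed. Figures were drawn with Python 3.11.15.

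Transcripts were to be named by protein names, gene lists and a panel, and failing names by at most 2 IDs that rose and 2 that fell per comparison. With no names in the files the latter applied, and the 2 with the largest rise and the 2 with the largest fall were taken among those called and lying on the same side of the other group's mean on every array of the first group. Others are said to have been chosen after their values were seen. Where a transcript was above background on no array of the lower group, the fold is a lower bound taken at the dimmest signal above background on each array, and where it was saturated the fold is a lower bound too. Differences fitted for these under other settings give no size. The 21 gene lists and 12 gene panel patterns prepared beforehand matched 0 probes, since the files pair no probe with a gene name, and they were left out.

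Slides and scan days were read from the headers, and a scan session is the arrays of 1 slide with the same scan time. Scanning periods 1 and 2 were told apart by the Feature Extraction version, 10.5.1.1 and 10.7.3.1, and no scan day held arrays of both. Slides, scan days and scan sessions were used as fixed blocks, as was the scanning period, and comparisons were also fitted within single slides. The precision of a value is limited by the number of arrays, 3 per exposed group, and at the low end by signal over background, with 68.3% to 92.4% of probes above background per array. With effects added to simulated data for Cu at the EC90 against the controls, the fit recovered 26.1% of 2-fold and 79.7% of 4-fold changes with 3.19% false calls, and 12.1% and 56.8% with slide as a block. For Cu and Ni against Cd and Zn it recovered 75.1% of 2-fold changes, and 8.43% with slide as a block. The simulated arrays held independent noise, with an effect of slide only for the fits with slide as a block. Batches as in the real arrays were not simulated, so 3.19% is not the share of false calls in the real comparison.

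Overlaps were counted between exposures against the shared controls, and compared with 200 simulations of unchanged groups set against the same controls and with 10 splits of the controls used both ways. Each comparison was refitted on other splits of its arrays, all 84 or 10 where there were that many and otherwise 100 with the real one included. The groups, tests, rule for named transcripts and a first set of other settings were fixed before the data were examined. That set held quantile normalisation, median scaling, normexp background correction with an offset of 50, no filter or a stricter filter on dim probes, slide, scan date and replicate number as blocks, a fit of the compared groups alone, array weights, a 2-fold threshold, an adjusted p under 0.01 for the overlap, adjustment over the 8 exposures together, the authors' deposited values, and leaving out each array in turn. For normexp the mean signal was to be used, but the deposited files hold the median signal, which was used. A further 7 settings were chosen after seeing the data: the scanning period as a block, the scan session as a block, fits within 1 scanning period, near-identical replicates averaged, slide as a block with quantile normalisation, both doubted arrays (Cu_EC50 replicate 3 and Cd_EC50 replicate 3) left out, and the 75th percentile over spots. The last was chosen after both versions had been computed.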

Results

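Gene expression was measured in adults of Enchytraeus albidus, a small segmented worm of soil known as a potworm, after 4 days in soil spiked with a metal. Copper (Cu), nickel (Ni), cadmium (Cd) and zinc (Zn) were each given at their EC50 and EC90, the concentrations that lower reproduction by 50% and 90%. The series has 30 arrays of whole worms, with 3 arrays for each of the 8 exposures and 6 arrays of worms in clean soil, and the labels call them biological replicates. Each array reads 1035 probes for worm transcripts, and 892 of them were bright enough to be tested. The files pair no probe with a gene name, so transcripts are given by their probe IDs. The comparisons ask which transcripts each metal changes, whether the higher concentration changes more, and how Cu and Ni differ from Cd and Zn. Transcripts said to have risen or fallen passed limma's test at an adjusted p under 0.05. The share of probes well above background ran from 68.3% to 92.4% over the 30 arrays, with a median of 82.1%. The number of arrays limits the precision of each value.

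The arrays were scanned in 2 periods, and these followed the metals. All arrays of Cu and Ni were scanned in period 2 with 2 controls, and all arrays of Cd and Zn in period 1 with 4 controls. Within these periods the headers give 5 slides, 4 scan days and 12 scan sessions. With slide as a block each exposure was set against 2 controls. With scan session as a block Cu and Ni were linked to control 1 alone and Cd to control 4 alone, and Zn to controls 5 and 6, while controls 2 and 3 had no weight. On slides 4 and 5 the control and at least 1 exposure had a single array each, so values there are given without a test, except for Cu against Ni. On the first principal component, which held 46.2% of the variance, the 6 EC90 arrays of Cu and Ni lay between 13.1 and 38.9, and the controls between -28.3 and -0.304. The EC50 arrays of Cu and Ni were spread from within the range of the controls to within that of the EC90 arrays. Cu_EC50 replicate 2 (session 9) and Ni_EC50 replicates 1 (session 12) and 2 (session 9) lay between 24.2 and 29.7. Cu_EC50 replicate 1 (session 7), Cu_EC50 replicate 3 (session 12) and Ni_EC50 replicate 3 (session 8) lay at 2.54, -9.96 and -5.67.

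**Figure D1:**
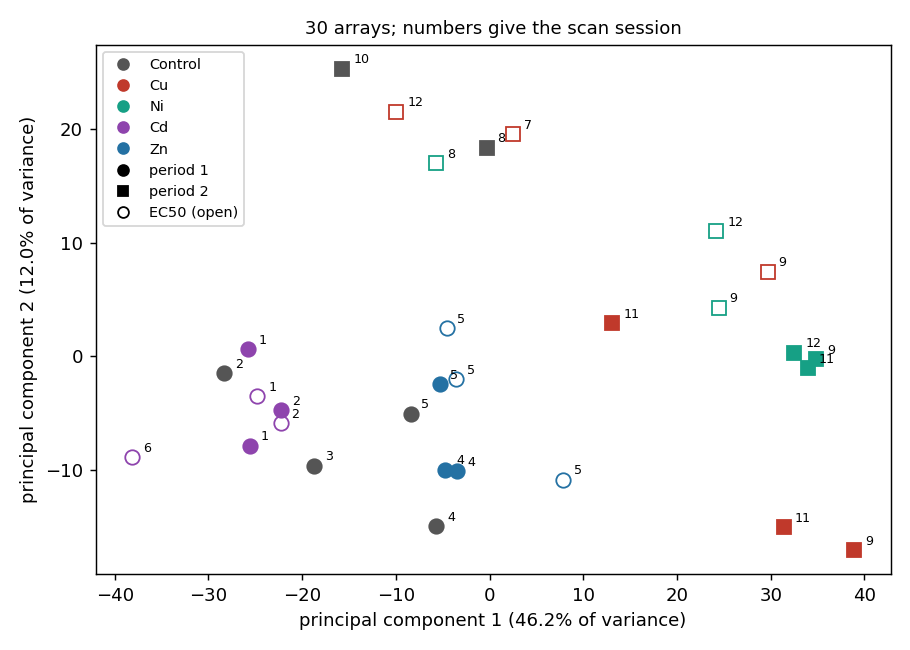
Each point is 1 of the 30 arrays, placed by its scores on principal component 1 (x axis, 46.2% of the variance) and 2 (y axis, 12%), both without units; colours give the metal or the control, open points the EC50 exposures, circles and squares scanning periods 1 and 2, and numbers the scan session. The EC90 arrays of Cu and Ni lie to the right, between 13.1 and 38.9 on component 1, and the EC50 arrays of Cu and Ni are spread from -9.96 to 29.7.

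At the EC50 of Cu, 45 transcripts rose and 35 fell against the controls. Contig123 rose 11.9-fold, by 3.58 ± 0.36 on the log2 scale (SE, n = 3 exposed and 6 control arrays, adjusted p = 4.51e-07). Ealb_Met_P7_E8_T7_2175287 rose 10.6-fold, by 3.40 ± 0.44 (adjusted p = 2.11e-05). Ealb_Met_P3_G5_SP6_2090365 fell by 3.83 ± 0.71 (adjusted p = 0.00412) and Ealb_Met_P4_D4_T7_2175252 fell by 3.37 ± 0.79 (adjusted p = 0.0201), and each was well above background on 1 of the 3 exposed arrays. The median change was 1.30 among the transcripts that rose and -2.22 among those that fell. The split between directions depended on the scaling, with 19 higher and 60 lower after median scaling, 61 and 86 after quantile normalisation, 25 and 34 with the percentile taken over spots, and 46 and 74 in the authors' deposited values. Once slide was a block, 2 transcripts were called, the same pair that rose most, and Contig123 had an adjusted p of 0.000712. Ealb_Met_P3_G5_SP6_2090365 and Ealb_Met_P4_D4_T7_2175252 then differed by -2.84 ± 0.83 (adjusted p = 0.322) and -2.59 ± 1.00 (0.415), smaller changes with a larger SE. With scan session as a block 4 transcripts were called, none of them among the 80, and Contig123 was higher by 1.98 ± 0.83 (adjusted p = 0.386). On slide 4 (2 exposed arrays and 1 control) and slide 5 (1 and 1) Contig123 was higher by 3.29 and 3.37. The count rested on single arrays. It was 2 without Cu_EC50 replicate 2, 52 without Cu_EC50 replicate 3, with 8 higher and 44 lower, and 123 without Cu_EC50 replicate 1, with 78 and 45. Replicate 3, on which the larger number of rises depended, read high for dim probes. Replicate 1 had the largest spread between spots of a probe of all 30 arrays. Its median SD over probes was 0.312 on the log2 scale, against a median of 0.0837 over the arrays. It was not among the doubted arrays left out together. Array weights and a fit of only the groups compared each gave 2 higher transcripts and none lower. Without controls 1 to 6 in turn the count was 127, 157, 13, 18, 29 and 35. Without Cu_EC50 replicate 2, Ealb_Met_P3_G5_SP6_2090365 and Ealb_Met_P4_D4_T7_2175252 had an adjusted p of 0.0629 and 0.126.

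At the EC90 of Cu, 98 transcripts rose and 263 fell, and 324 of these 361 changed by at least 2-fold. Ealb_Met_P7_G8_T7_2175288 rose 77.1-fold, by 6.27 ± 1.56 (adjusted p = 0.00567), and Ealb_Met_P7_C1_SP6_2090602 rose 69.5-fold, by 6.12 ± 1.64 (adjusted p = 0.00792). Both varied among the controls, with an SD of 3.34 and 3.58 on the log2 scale (n = 6). Ealb_Met_P7_G8_T7_2175288 was well above background on 4 of the 6 controls, so its size rests in part on signal at background. Ealb_Met_P3_G5_SP6_2090365 fell by 5.33 ± 0.71 (adjusted p = 2.43e-05), but was well above background on 1 of the 3 exposed arrays, so this size rests largely on signal at background. P1_B6_T7_1328848 was not well above background on any Cu_EC90 array and was at least 22.1-fold lower than the mean of the controls (adjusted p = 0.0279). The controls ran from -9.69 to 2.98, and the 3 above background for it were all of scanning period 1. Against the 2 controls of its own period, which were below background too, no fall can be given. The median change was 1.36 among the transcripts that rose and -1.87 among those that fell. The median of all 892 tested probes lay at -0.49 with the 75th percentile scaling, and at -0.04 after median scaling. Relative to the median, 187 transcripts were higher and 149 lower, and 98 of the 98 higher and 149 of the 263 lower transcripts kept their call. Quantile normalisation gave 132 higher and 109 lower, the authors' deposited values gave 129 and 101, and probes above background on every array gave 71 and 110.

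Once slide was a block, the Cu EC90 comparison held 64 higher and 266 lower transcripts, among them 233 of the 361 in the same direction. Ealb_Met_P7_G8_T7_2175288 and Ealb_Met_P7_C1_SP6_2090602 then rose by 9.19 ± 1.96 and 9.56 ± 1.83, and P1_B6_T7_1328848 had an adjusted p of 0.748, without a size since its signal was below background. For Ealb_Met_P7_G8_T7_2175288 the 9.19 rests on controls 1 and 2, and control 2 read lowest of all 6 controls, at -8.68. The excess of lower transcripts was not seen in 2 other fits. Slide as a block with quantile normalisation gave 113 higher and 91 lower, with 126 of the 361 in the same direction, and the fit within scanning period 2 gave 33 and 32, with 53 of the 361. On slide 4 (1 exposed array and 1 control) and slide 5 (2 and 1) Ealb_Met_P7_C1_SP6_2090602 was higher by 9.17 and 9.94. When scan session was a block 4 transcripts were called by limma, 1 of them among the 361. Ealb_Met_P7_G8_T7_2175288 and Ealb_Met_P7_C1_SP6_2090602 then differed by 6.78 ± 3.98 (adjusted p = 0.553) and 7.54 ± 3.92 (0.5), as large as before with an SE over 2 times as large, and Ealb_Met_P3_G5_SP6_2090365 by -1.38 ± 1.56 (0.7). Without Cu_EC90 replicate 1 the count was 112, and without Cu_EC90 replicate 2 it was 181. P1_B6_T7_1328848 had an adjusted p of 0.0535 without control replicate 4, 0.0922 without Cu_EC90 replicate 1 and 0.0749 without Cu_EC90 replicate 2.

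**Figure D2:**
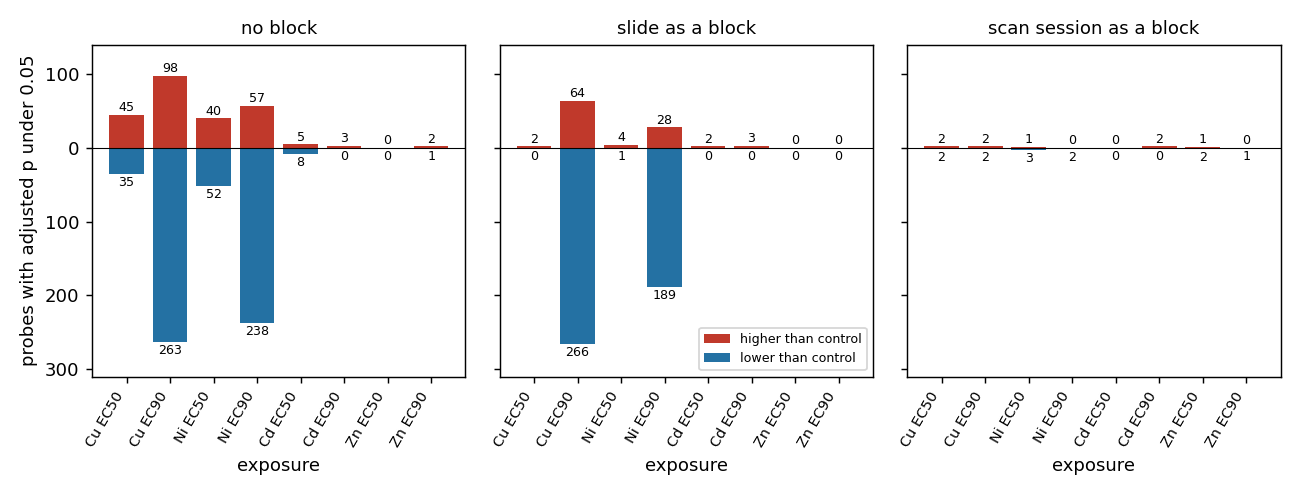
Bars give the number of probes (y axis) with an adjusted p under 0.05 for each exposure against the controls (x axis), higher upward in red and lower downward in blue, with no block, with slide as a block and with scan session as a block. The EC90 of Cu and of Ni hold 361 and 295 probes without a block, and 4 and 2 with scan session as a block.

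Between the EC90 and the EC50 of Cu, 25 transcripts were higher and 26 lower at the EC90. Ealb_Met_P7_C1_SP6_2090602 was higher by 6.72 ± 1.90 (n = 3 and 3, adjusted p = 0.0367) and Ealb_Met_P7_G8_T7_2175288 by 6.48 ± 1.81 (adjusted p = 0.036). Contig50 was lower, with a difference of -3.43 ± 0.89 (adjusted p = 0.0281), and so was Ealb_Met_P4_G7_SP6_2090089, with -3.40 ± 0.76 (adjusted p = 0.019). The median of all tested probes was -0.49, and median scaling gave 53 higher and 8 lower transcripts, quantile normalisation 33 and 12, and the authors' deposited values 24 and 10. Without the filter on dim probes there were 27 higher and 77 lower transcripts. After adding slide as a block 35 were higher and 156 lower, including all 51, and with quantile normalisation besides 52 and 38. On slide 4 (1 array at the EC90 and 2 at the EC50) and slide 5 (2 and 1) Ealb_Met_P7_C1_SP6_2090602 was higher by 7.20 and 5.92. In the fit with scan session as a block limma called 0 (149 at an unadjusted p under 0.05), while the changes stayed about as large, with a median ratio of 0.970 over the 51. Ealb_Met_P7_C1_SP6_2090602 then differed by 6.42 ± 2.42 (adjusted p = 0.23) and Ealb_Met_P4_G7_SP6_2090089 by -3.71 ± 1.06 (0.12), with 10 residual degrees of freedom in place of 21. Each of the 4 named calls ended without any 1 of Cu_EC50 replicates 1 and 3 and Cu_EC90 replicates 1 and 2, with an adjusted p between 0.0528 and 0.127. The count was 6, 247 and 15 without Cu_EC50 replicates 1, 2 and 3 in turn, and 6, 4 and 98 without Cu_EC90 replicates 1, 2 and 3.

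At the EC50 of Ni, 40 transcripts rose and 52 fell. P4_G7_SP6_1371468 rose 4.35-fold, by 2.12 ± 0.42 (n = 3 and 6, adjusted p = 0.00664). Ealb_Pest_P4_C8_SP6_2091879 was not well above background on any control array and was at least 1.45-fold higher with Ni (adjusted p = 0.00664). With normexp background correction it was not called (adjusted p = 0.994). Ealb_Met_P3_G5_SP6_2090365 fell by 3.97 ± 0.71 (adjusted p = 0.00384) and Ealb_Met_P3_A4_T7_2175231 fell by 3.94 ± 0.95 (adjusted p = 0.0134). Quantile normalisation gave 52 higher and 31 lower transcripts, the percentile over spots 33 and 72, normexp 22 and 18, probes above background on every array 33 and 19, and the authors' deposited values 40 and 27. In the fit with slide as a block 5 transcripts were called, 3 of them among the 92. P4_G7_SP6_1371468 then differed by 0.94 ± 0.34 (adjusted p = 0.139), Ealb_Met_P3_G5_SP6_2090365 by -2.98 ± 0.83 (0.104) and Ealb_Met_P3_A4_T7_2175231 by -2.16 ± 1.06 (0.295), each a smaller change, and Ealb_Pest_P4_C8_SP6_2091879 had an adjusted p of 0.135. Array weights gave 190 higher and 244 lower transcripts, while with only the groups compared limma called 0 (185 at an unadjusted p under 0.05). On slide 4 (2 exposed arrays and 1 control) and slide 5 (1 and 1) P4_G7_SP6_1371468 was higher by 1.07 and 0.59. With scan session as a block only Ni_EC50 replicate 3 and control 1 had a weight, and the 4 calls made then, 1 of them among the 92, are not read further. The count was 8, 12 and 213 without Ni_EC50 replicates 1, 2 and 3 in turn. It was 160 without control replicate 1, 52 without control 3, 35 without control 4 and 41 without control 5. Ealb_Pest_P4_C8_SP6_2091879 had an adjusted p of 0.0556 without Ni_EC50 replicate 1.

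At the EC90 of Ni, 57 transcripts rose and 238 fell, and 159 of those that fell changed by over 4-fold. Ealb_Met_P7_G8_T7_2175288 rose 29.8-fold, by 4.90 ± 1.56 (n = 3 and 6, adjusted p = 0.0191), and Ealb_Met_P7_C1_SP6_2090602 rose 22.1-fold, by 4.47 ± 1.64 (adjusted p = 0.0386), the same pair that rose most at the EC90 of Cu. The size for Ealb_Met_P7_G8_T7_2175288 rests in part on signal at background, since it was well above background on 4 of the 6 controls. Ealb_Met_P4_D4_T7_2175252 was not well above background on any Ni_EC90 array and was at least 34.0-fold lower than in the controls (adjusted p = 2.12e-06). P1_B6_T7_1328848, above background on 3 of the 6 control arrays, all of period 1, was at least 33.7-fold lower than their mean over all 6 (adjusted p = 0.0177). The 2 controls of period 2 were below background too, so that no fall can be given against these. The median of all tested probes was -0.21 with the 75th percentile scaling and 0.21 after median scaling. Relative to the median, 132 transcripts were higher and 187 lower, and all 57 higher and 187 of the 238 lower transcripts kept their call. Quantile normalisation gave 139 higher and 144 lower, and the authors' deposited values gave 182 and 126, with the larger number on the other side.

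Once slide was a block, the Ni EC90 comparison held 28 higher and 189 lower transcripts, among them 182 of the 295 in the same direction. Ealb_Met_P4_D4_T7_2175252 then had an adjusted p of 0.000711 and P1_B6_T7_1328848 of 0.661, without sizes since the exposed arrays were below background. Slide as a block with quantile normalisation gave 66 higher and 68 lower, with 94 of the 295 in the same direction. The fit within scanning period 2 gave 7 higher and 1 lower, 7 of them among the 295, and Ealb_Met_P4_D4_T7_2175252 had an adjusted p of 0.0503. On slide 4 (1 exposed array and 1 control) and slide 5 (2 and 1) Ealb_Met_P7_C1_SP6_2090602 was higher by 6.51 and 8.80. When scan session was a block 2 transcripts were called, none of them among the 295. Ealb_Met_P7_G8_T7_2175288 then differed by 5.46 ± 3.78 (adjusted p = 0.903) and Ealb_Met_P7_C1_SP6_2090602 by 6.03 ± 3.72 (0.839), as large as before with an SE over 2 times as large, and Ealb_Met_P4_D4_T7_2175252 had an adjusted p of 0.836. Without Ni_EC90 replicate 2 or without Ni_EC90 replicate 3 the count was 193. Ealb_Met_P7_C1_SP6_2090602 lost its call without any 1 of the 3 Ni_EC90 arrays or of controls 1, 2 and 4, with an adjusted p of up to 0.124. Ealb_Met_P7_G8_T7_2175288 had an adjusted p of 0.0589 and 0.0751 without Ni_EC90 replicates 1 and 2. P1_B6_T7_1328848 had 0.0549, 0.0552 and 0.0528 without Ni_EC90 replicates 1, 2 and 3.

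Between the EC90 and the EC50 of Ni, 2 transcripts were higher and 2 lower at the EC90. Ealb_Met_P7_E8_T7_2175287 was higher by 2.40 ± 0.51 (n = 3 and 3, adjusted p = 0.0222) and Contig123 by 2.26 ± 0.42 (adjusted p = 0.00779). P2_F4_T7_1328917 was lower, with a difference of -4.05 ± 0.76 (adjusted p = 0.00779), and so was Ealb_Pest_P3_H9_SP6_2091798, with -1.66 ± 0.38 (adjusted p = 0.0407). The median of all tested probes was -0.33, and median scaling kept 2 higher and 1 lower call while quantile normalisation kept 1 higher call, Contig123. The percentile over spots gave 2 higher and 1 lower transcript, and so did the fit without the filter on dim probes. Array weights gave 20 higher and 86 lower. When slide was a block all 4 were among 11 calls. On slide 4 (1 array at the EC90 and 2 at the EC50) and slide 5 (2 and 1) Contig123 was higher by 2.67 and 1.88. Once scan session was a block limma called 0 (92 at an unadjusted p under 0.05), while the changes stayed nearly as large, with a median ratio of 0.889 over the 4. Contig123 then differed by 1.89 ± 0.46 (adjusted p = 0.157) and P2_F4_T7_1328917 by -3.82 ± 0.85 (0.15). The count was 0 without Ni_EC50 replicate 3 or without Ni_EC90 replicate 2, and 2 without Ni_EC90 replicate 1. Contig123 had an adjusted p of 0.117 without Ni_EC50 replicate 3 and 0.0553 without Ni_EC90 replicate 2, and P2_F4_T7_1328917 had 0.0806 and 0.108. Ealb_Met_P7_E8_T7_2175287 had 0.209 without Ni_EC50 replicate 3, and 0.0606, 0.108 and 0.0776 without Ni_EC90 replicates 1, 2 and 3. Ealb_Pest_P3_H9_SP6_2091798 had 0.0519 to 0.302 without any 1 of the 6 arrays.

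At the EC50 of Cd, 5 transcripts rose and 8 fell. P3_C2_T7_1328984 rose 22.3-fold, by 4.48 ± 1.12 (n = 3 and 6, adjusted p = 0.0386), and Contig123 rose 7.42-fold, by 2.89 ± 0.36 (adjusted p = 2.5e-05). Ealb_Met_P7_D2_SP6_2090610 fell by 2.31 ± 0.47 (adjusted p = 0.0145) and Ealb_Met_P7_A11_SP6_2090675 fell by 2.20 ± 0.48 (adjusted p = 0.0249). They were well above background on 1 and 2 of the 3 exposed arrays, so these sizes rest in part on signal at background. Median scaling gave 4 higher and 16 lower transcripts, the percentile over spots 5 and 13, normexp 7 and 6, and the authors' deposited values 3 and 42. Array weights gave 164 higher and 123 lower, with a median SE over probes of 0.28 in place of 0.44, while a fit of only the groups compared gave 1 higher. Once slide was a block 2 transcripts remained, Contig123 and Ealb_Met_P7_E8_T7_2175287, both at an adjusted p of 0.0107. P3_C2_T7_1328984, Ealb_Met_P7_D2_SP6_2090610 and Ealb_Met_P7_A11_SP6_2090675 then differed by 0.51 ± 0.86, -0.65 ± 0.39 and -0.65 ± 0.49 (adjusted p = 0.999 for each). These values and those within slide 1, where the same 2 were called (2 exposed arrays and 2 controls), rest on Cd_EC50 replicates 1 and 2, since replicate 3 was alone on slide 3. Replicates 1 and 2 were nearly alike (r = 0.999 across probes), and with both averaged to 1 replicate 1 transcript was higher and 1 lower. With scan session as a block limma called 0 (39 at an unadjusted p under 0.05). Contig123 then differed by 3.06 ± 0.62 (adjusted p = 0.142), as large as before with a larger SE and control 4 alone for comparison. Without Cd_EC50 replicate 3, the dimmest array of the series, 2 transcripts were called, and P3_C2_T7_1328984, Ealb_Met_P7_D2_SP6_2090610 and Ealb_Met_P7_A11_SP6_2090675 had an adjusted p of 0.461, 0.17 and 0.362. The count was 20 without Cd_EC50 replicate 1, 3 without control 1, 2 or 5, 55 without control 3 and 29 without control 4. P3_C2_T7_1328984 had an adjusted p of 0.0937, 0.0883 and 0.0749 without controls 1, 2 and 5, and Ealb_Met_P7_A11_SP6_2090675 had 0.0722, 0.0688 and 0.0593.

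At the EC90 of Cd, 3 transcripts rose and none fell. Contig123 rose 69.7-fold, by 6.12 ± 0.36 (n = 3 and 6, adjusted p = 4.65e-12), and Ealb_Met_P7_E8_T7_2175287 rose 81.4-fold, by 6.35 ± 0.44 (adjusted p = 7.54e-11). Ealb_Met_P3_F12_SP6_2090417 rose 146-fold, by 7.19 ± 1.37 (adjusted p = 0.00659). It lay at 4.34 ± 0.69 (SD, n = 3) on the exposed arrays and at -2.85 ± 2.77 (n = 6) on the controls. Array weights gave 11 higher and 2 lower transcripts, replicate number as a block 8 and 3, and adjustment over the 8 exposures together 7 and 0. Contig123, the third of the 3 by size, was named after its value was seen. After adding slide as a block the same 3 transcripts were called, and within slide 1 Contig123 and Ealb_Met_P7_E8_T7_2175287 were called at an adjusted p of 4.93e-06. When scan session was a block both were called, at an adjusted p of 0.000114 and 0.000113, and Ealb_Met_P3_F12_SP6_2090417 differed by 2.44 ± 0.90 (0.774). With scanning period as a block it differed by 6.57 ± 1.48 (0.0543) and without Cd_EC90 replicate 2 by 6.80 (0.0956), nearly as much as before.

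Between the EC90 and the EC50 of Cd, 2 transcripts were higher at the EC90 and none lower. Array weights gave 103 higher and 84 lower, the 2 among them, with a median SE over probes of 0.23 in place of 0.51. Whether the nearly alike Cd_EC50 replicates 1 and 2 drove the weights was not tested. Ealb_Met_P7_E8_T7_2175287 was higher by 4.03 ± 0.51 and Contig123 by 3.23 ± 0.42 (n = 3 and 3), both at an adjusted p of 2.22e-05. Both were called with slide as a block (adjusted p = 0.000912), within slide 1 (0.000689) and with scan session as a block (0.00218), fits in which Cd_EC50 replicate 3 had no weight. With Cd_EC50 replicates 1 and 2 averaged 2 transcripts were called, the same pair. Both stayed called without any 1 of the 6 arrays, with a highest adjusted p of 0.000407.

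At the EC50 of Zn no transcript passed limma's test against the controls (88 had an unadjusted p under 0.05), while array weights gave 2 calls, adjustment over the 8 exposures together 9, and slide as a block with quantile normalisation 3. At the EC90 of Zn, 2 transcripts rose and 1 fell. P5_A12_T7_1330271 rose 3.71-fold, by 1.89 ± 0.35 (n = 3 and 6), and P2_A8_SP6_1371404 rose 2.95-fold, by 1.56 ± 0.28. P5_B10_T7_1329860 fell by 3.00 ± 0.57, and all 3 had an adjusted p of 0.00572. Quantile normalisation and the authors' deposited values each gave 2 higher and 2 lower transcripts, as did probes above background on every array. Array weights gave 250 calls, while with only the groups compared limma called 0 (60 at an unadjusted p under 0.05). In the fit with slide as a block limma called 0 at either concentration (88 at the EC50 and 38 at the EC90 had an unadjusted p under 0.05), and the 3 transcripts kept a median of 0.793 of their change. P2_A8_SP6_1371404 and P5_B10_T7_1329860 then differed by 1.35 ± 0.36 and -2.16 ± 0.69 (adjusted p = 0.363 and 0.581), and P5_A12_T7_1330271 had an SE of 0.45 in place of 0.35 (0.485). Within slide 2 no transcript was called at either concentration (125 at the EC50 and 61 at the EC90 had an unadjusted p under 0.05, with 3 exposed arrays and 2 controls). In the fit with scan session as a block 3 transcripts were called at the EC50 and 1 at the EC90, none of them among the 3, and P5_A12_T7_1330271, P2_A8_SP6_1371404 and P5_B10_T7_1329860 differed by 1.44 ± 0.41, 1.24 ± 0.38 and -2.32 ± 0.48 (adjusted p = 0.506, 0.532 and 0.167). Without Zn_EC90 replicate 1 or 2 the count was 0, with an adjusted p of 0.0709 and 0.0761 for each of the 3 transcripts, and without control 6 it was 11. Without Zn_EC90 replicate 3, P5_B10_T7_1329860 had an adjusted p of 0.0911. Zn_EC90 replicates 1 and 2 were nearly alike (r = 0.999 across probes), and with both averaged to 1 replicate limma called 0 (46 at an unadjusted p under 0.05), with an adjusted p of 0.0941 for each of the 3 transcripts. Without control 6 the EC50 comparison held 2 transcripts. Between the EC90 and the EC50 of Zn limma called 0 (74 had an unadjusted p under 0.05), and also with slide as a block (125), with scan session as a block (44) and within slide 2 (170). Array weights however gave 173 higher and 323 lower transcripts at the EC90, and slide as a block with quantile normalisation gave 1 lower. The median SE over probes was 0.21 with array weights and 0.51 without. Whether the nearly alike Zn_EC90 replicates 1 and 2 drove the weights was not tested.

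Contig123 and Ealb_Met_P7_E8_T7_2175287 were higher than in the controls at both concentrations of Cu, Ni and Cd. They were the only transcripts of the 892 called in the same direction for 3 metals, and none was called for all 4. Contig123 rose by 3.58 and 4.54 at the EC50 and EC90 of Cu, by 1.85 and 4.12 with Ni, and by 2.89 and 6.12 with Cd (SE 0.36 for each). Ealb_Met_P7_E8_T7_2175287 rose by 3.40 and 4.77 with Cu, by 1.61 and 4.01 with Ni, and by 2.32 and 6.35 with Cd (SE 0.44 for each). With Zn the differences were 0.64 and 0.69 for Contig123 (adjusted p = 0.542 and 0.497) and 0.66 and 0.80 for Ealb_Met_P7_E8_T7_2175287 (0.587 and 0.513), which did not pass the test. The rise from EC50 to EC90 was larger with Cd than with Zn by 3.18 ± 0.59 for Contig123 and by 3.89 ± 0.72 for Ealb_Met_P7_E8_T7_2175287 (adjusted p = 0.00654 for both). When slide was a block both were called for Cu and Cd at both concentrations and for Ni at the EC90, but not for Ni at the EC50, with 1.62 ± 0.48 and 1.52 ± 0.49 (adjusted p = 0.104 and 0.118). With scan session as a block both were called at the EC90 of Cd, and neither with Cu or Ni or at the EC50 of Cd. Contig123 then differed by 2.92 ± 0.86 and Ealb_Met_P7_E8_T7_2175287 by 2.94 ± 0.86 at the EC90 of Cu (adjusted p = 0.257 for both), and by 2.51 ± 0.82 and 2.29 ± 0.81 at the EC90 of Ni (0.547 for both), smaller changes with a larger SE and control 1 alone for comparison. At the EC50 of Ni, Contig123 had an adjusted p of 0.0536 without Ni_EC50 replicate 2, and Ealb_Met_P7_E8_T7_2175287 had 0.0539 without control replicate 4 and 0.224 and 0.166 without Ni_EC50 replicates 1 and 2. Both were singled out across exposures after their values were seen.

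**Figure D3:**
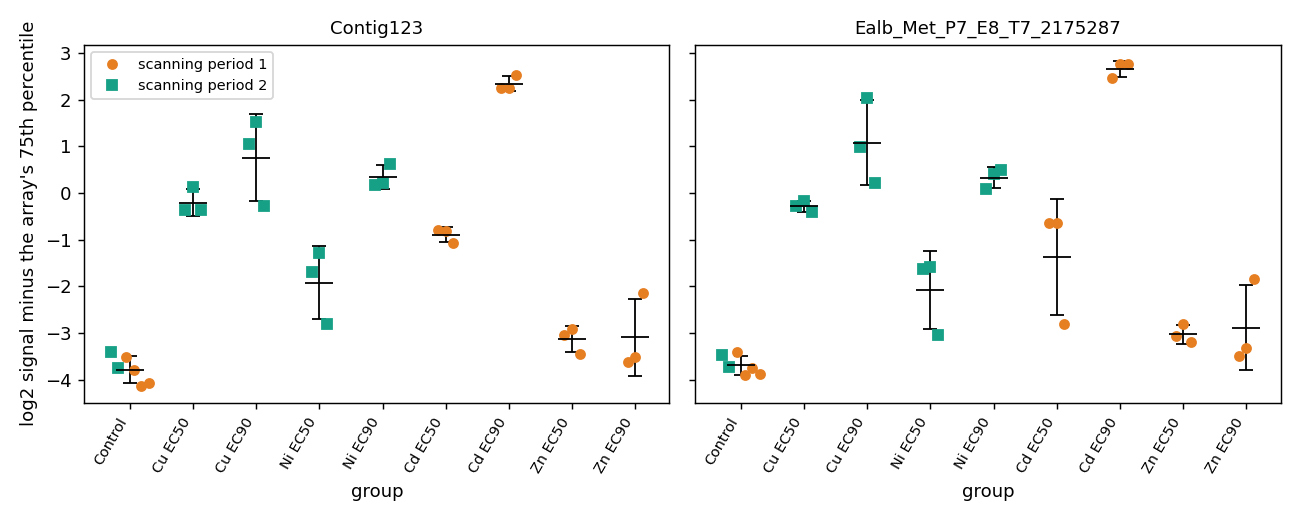
Points give the log2 signal of Contig123 (left) and Ealb_Met_P7_E8_T7_2175287 (right) on each array, relative to the array's 75th percentile (y axis), by group (x axis), with the mean and SD in black; circles and squares mark scanning periods 1 and 2. Contig123 lay at -3.78 in the controls and at 2.34 with Cd at the EC90, and at -3.14 and -3.09 with Zn.

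Cu and Ni were compared over both concentrations of each metal, and no transcript passed limma's test (69 had an unadjusted p under 0.05). The count was also 0 with slide as a block (104 at an unadjusted p under 0.05) and with scan session as a block (192), and within slides 4 and 5, with 3 arrays of each metal and 2 residual degrees of freedom, limma also called 0 (10 and 224 at an unadjusted p under 0.05). Without Ni_EC90 replicate 3 there was 1 call, as with the authors' deposited values and with replicate number as a block, and array weights gave 4.

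Between Cu and Cd, 173 transcripts were higher and 270 lower with Cu. Ealb_Met_P2_E3_SP6_2090254 was higher by 4.33 ± 1.15 (n = 6 and 6, adjusted p = 0.00335) and P3_D4_SP6_1371437 by 3.23 ± 0.41 (adjusted p = 4.09e-06). Ealb_Met_P3_F12_SP6_2090417 was lower, with a difference of -6.98 ± 1.12 (adjusted p = 5.27e-05), and so was P1_B6_T7_1328848, with -6.31 ± 1.72 (adjusted p = 0.00411). P1_B6_T7_1328848 was well above background on 1 of the 6 Cu arrays, so its values here and under other settings rest mostly on signal at background. Median scaling gave 268 higher and 210 lower transcripts, quantile normalisation 256 and 216, and the authors' deposited values 338 and 191. No slide held both metals. With slide as a block, where the controls alone link the metals, 5 transcripts were called, 2 of them among the 443, and Ealb_Met_P2_E3_SP6_2090254 and P1_B6_T7_1328848 changed sign, to -2.19 ± 1.87 and 2.84 ± 2.86 (adjusted p = 0.511 and 0.574), while P3_D4_SP6_1371437 differed by 0.42 ± 0.49 (0.629) and Ealb_Met_P3_F12_SP6_2090417 by -3.50 ± 1.63 (0.338). Scanning period as a block gave 7 calls, 4 of them among the 443. When scan session was a block 3 transcripts were called, none of them among the 443.

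Between Cu and Zn, 124 transcripts were higher and 133 lower with Cu. Ealb_Met_P2_E3_SP6_2090254 was higher by 5.02 ± 1.15 (n = 6 and 6, adjusted p = 0.0032) and P5_A4_T7_1329813 by 3.63 ± 0.68 (adjusted p = 0.000592). Contig51 was lower, with a difference of -4.16 ± 0.51 (adjusted p = 4.21e-06), and so was P2_F4_T7_1328917, with -3.71 ± 0.54 (adjusted p = 4.71e-05). The authors' deposited values gave 121 higher and 85 lower transcripts. No slide held both metals. After adding slide as a block 6 transcripts were called, 3 of them among the 257, and Contig51 differed by -2.52 ± 0.96 (adjusted p = 0.244), P2_F4_T7_1328917 by -2.25 ± 0.95 (0.299) and Ealb_Met_P2_E3_SP6_2090254 by 0.13 ± 1.84 (0.971), while P5_A4_T7_1329813 changed sign, to -0.62 ± 0.94 (0.75). Control 1 is 1 of the 4 controls used in that fit. For Contig51 it lay at -5.81 and the other controls between -3.41 and -2.67. Whether it carries the smaller difference was not tested. Scanning period as a block gave 4 calls, 3 of them among the 257. Once scan session was a block 3 transcripts were called, none of them among the 257. The count was 157 without Cu_EC50 replicate 2 and 167 without Zn_EC50 replicate 3.

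Between Ni and Cd, 155 transcripts were higher and 320 lower with Ni. Ealb_Met_P2_E3_SP6_2090254 was higher by 5.23 ± 1.15 (n = 6 and 6, adjusted p = 0.000528) and Ealb_Met_P4_D7_T7_2175256 by 3.08 ± 0.56 (adjusted p = 9.38e-05). P1_B6_T7_1328848 and P3_C2_T7_1328984 were not well above background on any array of Ni, and were at least 69.5-fold (adjusted p = 0.000513) and 51.2-fold (adjusted p = 1.46e-06) lower than with Cd. The median of all tested probes was -0.23 with the 75th percentile scaling and 0.25 after median scaling. Median scaling gave 333 higher and 252 lower transcripts, quantile normalisation 310 and 245, normexp 111 and 470, and the authors' deposited values 349 and 191. No slide held both metals. In the fit with slide as a block limma called 0 (164 at an unadjusted p under 0.05), and Ealb_Met_P2_E3_SP6_2090254 changed sign, to -1.29 ± 1.87 (adjusted p = 0.719), while Ealb_Met_P4_D7_T7_2175256 differed by 0.59 ± 0.80 (0.696). P1_B6_T7_1328848 and P3_C2_T7_1328984, below background with Ni, had an adjusted p of 0.83 and 0.658. With scanning period as a block 16 were higher and 96 lower, 99 of them among the 475, and with scan date as a block 11 and 71, with 71 among the 475. With scan session as a block 2 transcripts were called, none of them among the 475.

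Between Ni and Zn, 106 transcripts were higher and 189 lower with Ni. Ealb_Met_P2_E3_SP6_2090254 was higher by 5.92 ± 1.15 (n = 6 and 6, adjusted p = 0.000819). P3_F2_T7_1328987 was not well above background on any array of Zn and was at least 2.92-fold higher with Ni (adjusted p = 0.00375). Ealb_Met_P4_D4_T7_2175252 was lower, with a difference of -4.31 ± 0.65 (adjusted p = 7.18e-05), and so was Ealb_Met_P9_E12_SP6_2090775, with -4.31 ± 0.67 (adjusted p = 0.000107). They were well above background on 3 and 2 of the 6 Ni arrays, so their sizes, also with slide as a block, rest in part on signal at background. Quantile normalisation gave 147 higher and 129 lower transcripts, and the authors' deposited values 161 and 94. No slide held both metals. When slide was a block limma called 0 (169 at an unadjusted p under 0.05), and P3_F2_T7_1328987, below background with Zn, had an adjusted p of 0.988. Ealb_Met_P2_E3_SP6_2090254 then differed by 1.03 ± 1.84 (0.832), Ealb_Met_P4_D4_T7_2175252 by -3.73 ± 1.26 (0.152) and Ealb_Met_P9_E12_SP6_2090775 by -4.15 ± 1.13 (0.13), the last 2 nearly as much as before with a larger SE. Scanning period as a block also gave 0 (147). When scan session was a block 2 transcripts were called, none of them among the 295. Without Ni_EC50 replicate 1 the count was 190.

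Between Cd and Zn, 131 transcripts were higher and 104 lower with Cd. Ealb_Met_P3_F12_SP6_2090417 was higher by 8.30 ± 1.12 (n = 6 and 6, adjusted p = 3.12e-05). Ealb_Met_P3_A4_T7_2175231 was saturated on every array of Cd and was at least 47.1-fold higher than with Zn (adjusted p = 3.12e-05). Contig129 was lower, with a difference of -3.28 ± 1.12 (adjusted p = 0.0344), and so was Ealb_Pest_P9_F6_SP6_2091032, with -2.82 ± 0.94 (adjusted p = 0.0304). The median of all tested probes was 0.16 with the 75th percentile scaling and -0.27 after median scaling, which gave 92 higher and 218 lower transcripts. Quantile normalisation gave 128 and 179, normexp 174 and 41, probes above background on every array 85 and 44, and the authors' deposited values 107 and 198. No slide held both metals. With slide as a block 2 transcripts were called, both among the 235. Ealb_Met_P3_A4_T7_2175231, saturated with Cd, then had an adjusted p of 0.0502, and Ealb_Met_P3_F12_SP6_2090417 differed by 6.32 ± 1.63 (0.12), a smaller change with a larger SE. Contig129 differed by -6.20 ± 2.34 (0.548), and Ealb_Pest_P9_F6_SP6_2091032 by -0.18 ± 1.88 (0.997), where little of the change was left. In the fit with scan session as a block 3 transcripts were called, all among the 235, with Ealb_Met_P3_A4_T7_2175231 at an adjusted p of 0.0437. With scanning period as a block 257 were called, 234 of them among the 235. The count was 126 without Cd_EC50 replicate 3, 155 without Cd_EC90 replicate 1 and 138 without Zn_EC50 replicate 3. Contig129 lost its call without any 1 of 8 arrays, namely replicates 2 and 3 of Cd_EC50, Cd_EC90 and Zn_EC50 and replicates 1 and 2 of Zn_EC90 (adjusted p up to 0.0867). Ealb_Pest_P9_F6_SP6_2091032 lost its call without Cd_EC50 replicate 3, Cd_EC90 replicates 1 and 2, Zn_EC50 replicates 2 and 3 or Zn_EC90 replicates 1 and 2 (adjusted p up to 0.103).

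Cu and Ni together were set against Cd and Zn together, the contrast in the title of the series. With Cu and Ni 200 transcripts were higher and 322 lower, the largest count of the 19 comparisons. Ealb_Met_P2_E3_SP6_2090254 was higher by 5.12 ± 0.81 (n = 12 and 12, adjusted p = 1.81e-05) and P3_D4_SP6_1371437 by 2.77 ± 0.29 (adjusted p = 9.75e-08). Ealb_Met_P3_G5_SP6_2090365 was lower, with a difference of -4.91 ± 0.41 (adjusted p = 8.58e-09), and so was Ealb_Met_P4_D4_T7_2175252, with -4.72 ± 0.46 (adjusted p = 5e-08). Each was well above background on 5 of the 12 Cu and Ni arrays, so these sizes rest in part on signal at background. Median scaling gave 264 higher and 263 lower transcripts, quantile normalisation 273 and 254, normexp 163 and 429, and the authors' deposited values 352 and 220. The metals lie in separate scanning periods, so the difference holds that between periods, and only the controls link them. Each array of period 1 had 20 to 45 saturated probes and each array of period 2 had 0. For saturated probes a correction taken from the controls may not hold. With scanning period as a block limma called 0 (167 at an unadjusted p under 0.05), and the 2 control arrays of period 2 against the 4 of period 1 set the correction. After adding slide as a block 1 transcript was called and with scan session as a block 3, none of them among the 522. With period as a block Ealb_Met_P3_G5_SP6_2090365 and Ealb_Met_P4_D4_T7_2175252 differed by -3.70 ± 0.94 and -3.83 ± 1.08 (adjusted p = 0.0701 and 0.0811), P3_D4_SP6_1371437 by 0.33 ± 0.41 (0.661) and Ealb_Met_P2_E3_SP6_2090254 by -0.47 ± 1.46 (0.883).

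The overlap between exposures was counted in probes called in the same direction against the shared controls. At the EC90, Cu and Ni shared 42 higher and 165 lower transcripts and none in opposite directions. Independent lists of these lengths would share 6.26 and 70.2. Simulated unchanged groups set against the same controls shared 0, which is close to fixed by construction, since unchanged groups give few or no calls. The fold changes of Cu and Ni at the EC90 had a correlation of 0.860 across probes, against 0.328 in the simulation, and a covariance of 1.88 against 0.10. With the controls split so that each metal had its own 3, the correlation was 0.761 on average and lay between 0.592 and 0.872. Once slide was a block 156 transcripts were shared and the correlation was 0.881. Both metals were then set against the same 2 controls, and unchanged groups were not simulated for that fit, so 0.328 is not its no-change value. The arrays of Cu and Ni share scanning period 2, slides 4 and 5 and sessions 9, 11 and 12, while 4 of the 6 controls are of period 1. Neither the simulation nor the split controls hold such a shared batch, so these overlaps include whatever batch adds to both metals. At the EC50, Cu and Ni shared 21 higher and 12 lower transcripts (expected 2.02 and 2.04), with a correlation of 0.799 against 0.334, a covariance of 0.81 against 0.10, and a correlation of 0.607 with split controls. Once slide was a block they shared 0, with few calls left to share, and the correlation was 0.769, again with the same 2 controls for both and no simulated value for that fit. The EC50 and EC90 of Cu shared 23 higher and 30 lower transcripts (expected 4.94 and 10.3) and 1 in opposite directions, with a correlation of 0.637 against 0.334, a covariance of 0.88 against 0.10, and 0.510 with split controls, and 2 shared with slide as a block. Those of Ni shared 19 and 50 (expected 2.56 and 13.9), with a correlation of 0.804 against 0.337, a covariance of 1.28 against 0.10, and 0.675 with split controls, and 3 shared with slide as a block. Cu and Cd at the EC90 shared 2 higher transcripts, Contig123 and Ealb_Met_P7_E8_T7_2175287 (expected 0.330), as did Ni and Cd (expected 0.192). Their fold changes were correlated at -0.269 for Cu and -0.371 for Ni, against 0.328 and 0.336 in the simulation, with covariances of -0.27 and -0.39 against 0.10 in both. With split controls these correlations were -0.327 and -0.405, and with slide as a block, where Cd has other controls than Cu and Ni, -0.0511 and 0.0357. Over the 2 concentrations of each metal, 60 transcripts were higher and 170 lower for both Cu and Ni and for neither Cd nor Zn, 56 and 98 for Cu alone, and 16 and 70 for Ni alone. After adding slide as a block these were 24 and 130, 38 and 136, and 4 and 59. A call for Cu alone or Ni alone is not a difference between the metals. Compared directly over both concentrations, no transcript passed limma's test between Cu and Ni (69 had an unadjusted p under 0.05).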

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

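The tests in this part were chosen after the results they bear on had been seen, except that slide as a block, a fit of only the groups compared and leaving out 1 array were planned, with the bounds for reading them set afterwards. In the EC90 arrays of Cu and Ni against the controls, slide and scan session were weighed against the exposure. With slide as a block 233 of 361 calls for Cu and 182 of 295 for Ni stayed in the same direction, so slide alone does not account for those that stayed. With quantile normalisation besides, 126 of 361 and 94 of 295 stayed, too few under the same bound to decide, so slide is not excluded for the others. Scan session is open: over the called probes, the EC50 arrays from sessions 9 and 12 differed from those of sessions 7 and 8 with a slope of 0.383 on the Cu fold changes (0.208 on Cu arrays, 0.558 on Ni arrays), and of 0.349 on the Ni fold changes (0.132 and 0.566). With session as a block, where control 1 alone links Cu and Ni to the controls, the median size of the called changes went from 1.75 to 1.00 for Cu and from 2.29 to 0.78 for Ni, while the median SE rose from 0.51 to 0.99 and from 0.57 to 1.07. The controls and the EC90 arrays of Cu and Ni shared no session, so an effect of session could make up part of these responses.

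The differences between metals lie across scanning periods or slides, and for Cu and Ni against Cd and Zn the controls of period 2 against those of period 1 had a slope of 0.368 on the fold changes of the 522 called probes (0.214 to 0.521), with the same sign in 74.3% of them. For Cd against Zn the controls on the slide of Cd against those on the slide of Zn had a slope of 0.581 (0.410 to 0.752), with the same sign in 95.3% of the 235 called probes. Between the controls alone 75 probes were called across periods (207 at an unadjusted p under 0.05) and 13 across these slides (160). With scanning period as a block the median size of the 522 changes went from 1.22 to 0.67 and the median SE from 0.28 to 0.61, and for Cd against Zn with slide as a block from 1.40 to 0.32 and from 0.38 to 0.63. Batch could therefore carry part of either difference, and how much is metal stays undecided.

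Contig123 and Ealb_Met_P7_E8_T7_2175287 were weighed as a pair. For Cd at the EC90, scan session as a block left an adjusted p of 0.000114 for the weaker of the pair, with control 4 alone for comparison. Contig123 ran from -4.14 to -3.42 over the 6 controls, each of another session, and from 2.24 to 2.53 over the 3 Cd_EC90 arrays. Session alone therefore does not account for the rise there, though 2 of these 3 arrays lay in session 1, which holds no control. For Cu and Ni at the EC90 the adjusted p with session as a block was 0.257 and 0.547, with changes in Contig123 of 2.92 ± 0.86 and 2.51 ± 0.82 left. Session stays open for part of the rise with Cu and Ni, since their sessions 9, 11 and 12 hold no control. Their deviations from the group means had a correlation of 0.792 over the 30 arrays (permutation p = 1e-05, the smallest that 1e+05 permutations can give, rank correlation 0.829). It was 0.727 without the 2 most extreme arrays, Cu_EC90 replicate 3 and Zn_EC90 replicate 3, and 0.698 and 0.933 in periods 1 and 2. Ealb_Met_P7_E8_T7_2175287 ranked 1 of 891 probes by correlation with Contig123, so both probes may read 1 transcript, which the files cannot decide.

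Whether another grouping of the arrays by chance could give as many calls was tested by refitting on other splits. The splits went against chance for Cu at the EC90 (361 calls, 1 of 84 splits with as many, highest other 192). They also did for Ni at the EC90 (295, 1 of 84, highest other 146, from controls 2, 3 and 4 against the rest). In both the real split alone had as many, a share of 0.0119. That is the smallest that 84 splits can give, so over 19 comparisons they do not exclude chance. For Ni at the EC50 (92, 4 of 84, highest other 136, with control 6 beside Ni_EC50 replicates 1 and 2) the share of splits lay barely under 1 in 20 among 19 comparisons. Limma called 0 there with only the groups compared (185 at an unadjusted p under 0.05), 1 with scanning period as a block and 8 without Ni_EC50 replicate 1, so chance is left open for it. The splits did not go against chance for Cu at the EC50 (80, 5 of 84, highest other 124), Cd at the EC50 (13, 8 of 84, highest other 198), Cd at the EC90 by the count (3, 6 of 84, highest other 60) and Zn at the EC90 (3, 7 of 84, highest other 67). For Contig123 and Ealb_Met_P7_E8_T7_2175287 at the EC90 of Cd the splits did go against chance. The second smallest adjusted p of any transcript was 7.54e-11 there, with 1 of 84 splits as low and 0.00218 as the lowest other. With 0 real calls, Zn at the EC50 (84 of 84, highest other 33) and Cu against Ni (100 of 100, highest other 215) have as many in every split by construction, which says nothing about chance. The highest split of Cu against Ni set the 4 arrays of session 9 on 1 side with 1 of the 3 arrays each of sessions 11 and 12. For Cd at the EC50 and the EC90 the highest split set controls 1, 2 and 5 apart, and for Zn controls 2, 3 and 4. The 10 splits of EC90 against EC50 are too few to tell, with 51 real and 174 as the highest other for Cu (2 of 10), 4 and 1 for Ni (1 of 10), 2 and 0 for Cd (1 of 10) and 0 and 0 for Zn (10 of 10). Between metals the splits went against chance for Cu and Cd (443, 1 of 100, highest other 299), Ni and Cd (475, 1 of 100, 401), Cd and Zn (235, 1 of 100, 33) and Cu and Ni against Cd and Zn (522, 1 of 100, 24). In each the real split alone had as many, the smallest share that 100 splits can give (0.01), so chance is not excluded over 19 comparisons. Chance is left open for Cu and Zn (257, 2 of 100, 338) and Ni and Zn (295, 2 of 100, 334), where another split called more than the real one. Each of these other splits was the real one with 1 array of each metal exchanged. It keeps most of the real contrast and decides little about chance. The highest other splits of Cu and Cd and of Ni and Cd were of this kind too. These splits do not separate metal from scanning period or slide.

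Contig51 had 1 control far from the others: control replicate 1 lay apart by 0.766 of the range of the 6 controls, more than Dixon's test allows. It was 1 of 34 control groups tested, and chance raises about 1 in 20. The step from EC50 to EC90 differed between Cu and Cd in 2 transcripts (P5_G12_T7_1330277 by 3.14 and Ealb_Pest_P2_D8_T7_2175107 by 1.97), between Cu and Zn in 6, and between Cd and Zn in 2 (Contig123 and Ealb_Met_P7_E8_T7_2175287). With slide as a block these counts were 32, 31 and 2. Between Cu and Ni, Ni and Cd, and Ni and Zn limma called 0 (58, 52 and 76 at an unadjusted p under 0.05). Outside the worm probes, the spike-in controls E1A_r60_3 and E1A_r60_a104 read 6.90 and 8.10 on the log2 scale on Cu_EC50 replicate 3, above the highest control arrays at 2.88 and 1.83.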

How the results depend on the processing

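Of the values of named transcripts under other settings, 1252 kept their direction and their side of the threshold, 322 kept their direction and lost the call, and 41 changed direction. Of the counts, 371 stayed within 1.5 times the reported one and 182 did not. The cause was not tested for any of these, except that fits of fewer groups or arrays and stricter filters test fewer probes or hold fewer arrays by construction. Exposures rest on 2 controls with slide as a block, on 2 (Cu and Ni) or 4 (Cd and Zn) with period, and on 1 (Cu, Ni and Cd) or 2 (Zn) with session, and signal over background limits the dim probes. The scanning period, the scan session, fits within 1 period, slide with quantile normalisation, averaged near-identical replicates, both doubted arrays left out and the percentile over spots were chosen after seeing the data. The labels' replicate numbers do not pair the arrays: over 108 same-numbered pairs the median correlation of deviations was 0.0330, against -0.0112 for other numbers, and 10 of 30 arrays were closest to an array of their own number.

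Counts of called transcripts that moved by over 1.5 times were as follows, and the cause was not tested. Under quantile normalisation: Cu_EC50 147, Cd_EC50 38, Ni EC90 against EC50 1, transcripts called in the same direction for at least 3 metals 4. For normexp: Cu_EC50 30, Ni_EC50 40, Ni EC90 against EC50 7. Using slide as a block: Cu_EC50 2, Ni_EC50 5, Cd_EC50 2, Zn_EC90 0, Cu EC90 against EC50 191, Ni EC90 against EC50 11, Cu against Cd 5, Cu against Zn 6, Ni against Cd 0, Ni against Zn 0, Cd against Zn 2, Cu and Ni against Cd and Zn 1. Given scan date as a block: Cu_EC50 2, Ni_EC50 1, Cd_EC50 2, Zn_EC50 1, Zn_EC90 1, Cu EC90 against EC50 127, Ni EC90 against EC50 8, Cu against Cd 9, Cu against Zn 5, Ni against Cd 82, Ni against Zn 0, Cd against Zn 148, Cu and Ni against Cd and Zn 0. Under replicate number as a block: Cu_EC50 6, Cu_EC90 238, Ni_EC50 1, Cd_EC50 64, Cd_EC90 11, Zn_EC90 11, Ni EC90 against EC50 2, Cu against Ni 1. For only the groups compared in the fit: Cu_EC50 2, Cu_EC90 180, Ni_EC50 0, Cd_EC50 1, Zn_EC90 0, Cu EC90 against EC50 6, Cd EC90 against EC50 4. Using array weights: Cu_EC50 2, Cu_EC90 544, Ni_EC50 434, Ni_EC90 443, Cd_EC50 287, Cd_EC90 13, Zn_EC50 2, Zn_EC90 250, Ni EC90 against EC50 106, Cd EC90 against EC50 187, Zn EC90 against EC50 496, Cu against Ni 4, Cu against Zn 446, Ni against Zn 688, Cd against Zn 598. Given scanning period as a block: Cu_EC50 2, Cu_EC90 180, Ni_EC50 1, Ni_EC90 173, Cd_EC50 2, Zn_EC90 1, Cu against Cd 7, Cu against Zn 4, Ni against Cd 112, Ni against Zn 0, Cu and Ni against Cd and Zn 0. Under scan session as a block: Cu_EC50 4, Cu_EC90 4, Ni_EC50 4, Ni_EC90 2, Cd_EC50 0, Zn_EC50 3, Zn_EC90 1, Cu EC90 against EC50 0, Ni EC90 against EC50 0, Cd EC90 against EC50 4, Cu against Cd 3, Cu against Zn 3, Ni against Cd 2, Ni against Zn 2, Cd against Zn 3, Cu and Ni against Cd and Zn 3. For fits within 1 scanning period: Cu_EC50 2, Cu_EC90 65, Ni_EC50 0, Ni_EC90 8, Cd_EC50 2, Zn_EC90 1. Using slide as a block with quantile normalisation: Cu_EC50 10, Cu_EC90 204, Ni_EC50 33, Ni_EC90 134, Cd_EC50 2, Zn_EC50 3, Zn_EC90 0, Cu EC90 against EC50 90, Zn EC90 against EC50 1, Cu against Cd 9, Cu against Zn 17, Ni against Cd 17, Ni against Zn 1, Cd against Zn 8, Cu and Ni against Cd and Zn 45. Given probes above background on every array: Cu_EC90 181, Ni_EC50 52, Ni_EC90 181, Cd against Zn 129. Under authors' deposited values: Cu_EC90 230, Cd_EC50 45, Ni EC90 against EC50 2, Cu against Ni 1. For adjustment over the 8 exposures together: Cu_EC90 190, Cd_EC50 44, Cd_EC90 7, Zn_EC50 9, Zn_EC90 15. Using median scaling: Ni_EC50 160, Cd_EC50 20. Given both doubted arrays left out: Ni_EC50 168, Cd_EC50 2, Cu EC90 against EC50 30, Ni EC90 against EC50 10, Cd against Zn 149. Under near-identical replicates averaged: Cd_EC50 2, Zn_EC90 0. For no filter on dim probes: Cu EC90 against EC50 104. Using a 2-fold threshold: Cu against Zn 168, Cu and Ni against Cd and Zn 325.

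Without each array in turn the counts ran over these ranges, and the cause was not tested: Cu_EC50 2 to 157, Cu_EC90 112 to 350, Ni_EC50 8 to 213, Ni_EC90 193 to 315, Cd_EC50 2 to 55, Cd_EC90 2 to 4, Zn_EC50 0 to 2, Zn_EC90 0 to 11, Cu EC90 against EC50 4 to 247, Ni EC90 against EC50 0 to 4, Cd EC90 against EC50 2 to 2, Zn EC90 against EC50 0 to 0, Cu against Ni 0 to 1, Cu against Cd 380 to 466, Cu against Zn 157 to 319, Ni against Cd 434 to 504, Ni against Zn 190 to 365, Cd against Zn 126 to 233, Cu and Ni against Cd and Zn 498 to 548.

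Transcripts that changed direction had these log2 differences, and the cause was not tested. Those below background in 1 group (Ealb_Pest_P4_C8_SP6_2091879 in Ni_EC50, P1_B6_T7_1328848 in Cu_EC90 and in Ni against Cd, P3_C2_T7_1328984, P3_F2_T7_1328987) give no size. Their values below are fitted on signal at background and are not reversals of a measured change. P1_B6_T7_1328848 in Cu against Cd was above background on 1 of the 6 Cu arrays, so its values below are no measured size either. Ealb_Met_P4_D4_T7_2175252 in Cu_EC50 was 0.65 (session). P1_B6_T7_1328848 in Cu_EC90 was 0.45 (session). Ealb_Pest_P4_C8_SP6_2091879 in Ni_EC50 was -0.0051 (normexp). Ealb_Met_P2_E3_SP6_2090254 in Cu against Cd was -2.19 (slide), -1.48 (scan date), -1.27 (period), -3.04 (session), -2.28 (slide with quantile). P3_D4_SP6_1371437 in Cu against Cd was -0.62 (session). P1_B6_T7_1328848 in Cu against Cd was 2.84 (slide), 2.07 (scan date), 1.73 (period), 7.62 (session), 3.28 (slide with quantile). Ealb_Met_P2_E3_SP6_2090254 in Cu against Zn was -0.58 (scan date), -0.58 (period). P5_A4_T7_1329813 in Cu against Zn was -0.62 (slide), -0.40 (session), -0.68 (slide with quantile). Ealb_Met_P2_E3_SP6_2090254 in Ni against Cd was -1.29 (slide), -0.58 (scan date), -0.37 (period), -2.42 (session), -1.39 (slide with quantile). Ealb_Met_P4_D7_T7_2175256 in Ni against Cd was -0.73 (session). P1_B6_T7_1328848 in Ni against Cd was 1.28 (slide), 0.51 (scan date), 0.16 (period), 5.34 (session), 2.51 (slide with quantile). P3_C2_T7_1328984 in Ni against Cd was 0.066 (session), 0.32 (slide with quantile). P3_F2_T7_1328987 in Ni against Zn was -0.11 (slide), -1.35 (session). Ealb_Pest_P9_F6_SP6_2091032 in Cd against Zn was 1.12 (session). Ealb_Met_P2_E3_SP6_2090254 in Cu and Ni against Cd and Zn was -0.58 (slide), -0.58 (scan date), -0.47 (period), -1.13 (session), -0.60 (slide with quantile). P3_D4_SP6_1371437 in Cu and Ni against Cd and Zn was -0.59 (session).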

Other observations

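Tests in this part were chosen after the results had been seen. Probe IDs fall in 4 kinds by the start of their name, with 157 tested probes named Contig, 290 Ealb_Met, 165 Ealb_Pest and 280 with other names. Transcripts with other names were called lower less often at the EC90 of Cu (37 of 280 against 226 of 612) and of Ni (24 of 280 against 214 of 612). Fisher's exact test gave an adjusted p of 1.4e-12 and 3.74e-17 over 32 tests, though probes of 1 array are not independent replicates. Their median change was 0.22 against -0.97 for Cu and 0.10 against -0.50 for Ni. Within classes of similar signal level the odds ratio of being called lower was 0.329 for Cu and 0.202 for Ni. With slide as a block it was 0.130 and 0.107, and with scan session as a block 0 and 2 transcripts of the 2 kinds were called lower for each metal, too few to compare.

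The median SD over probes was 0.68 among the 6 controls and 0.57 within exposed groups on the log2 scale, and the SD was over 2 in 19 and 6 probes. Zn_EC90 replicates 1 and 2 had a correlation of 0.999 and Cd_EC50 replicates 1 and 2 of 0.999, and their median difference was 2.73 and 3.76 times the error expected from spots. Other pairs of replicates differed by 9.82 times or more.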
